A study of Homo sapiens with 10 samples.

How the data were processed

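Total RNA of 2 human breast cancer cell lines, SKBR3 and MDA-468, was profiled on Affymetrix whole-transcript expression arrays 48 h after transient transfection with a control double-stranded RNA oligonucleotide (siControl) or with a duplex against Che-1 (siChe-1), the protein encoded by AATF. Both lines are described in the labels as breast cancer cells expressing mutant p53. Per the labels' protocols, RNA was extracted with Trizol and 6 micrograms of it were labelled with biotin. There were 10 arrays: 2 SKBR3 siControl, 2 SKBR3 siChe-1, 3 MDA-468 siControl and 3 MDA-468 siChe-1. Groups and replicate numbers were taken from the labels. Nothing in the labels says that replicates of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

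The deposited values are log2 probe set intensities that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background of each array, quantile-normalizes arrays that are processed together and summarises the probes of a probe set. The versions of these tools, and which arrays were normalized together, are not given in the sources used here. Array medians lay between 6.36 and 6.45 in SKBR3 and between 6.87 and 6.94 in MDA-468, so the lines do not share a value distribution. Comparisons were therefore made within each line, and fold changes rather than levels were set against each other across lines. Levels were set against the filter level given below, which was taken over all arrays and which SKBR3 values, with their lower array medians, fall below more readily. For some genes the levels of both lines are printed, to show where each change started. The value table was the only file used. The number of arrays, and how far a probe set stands above background, limit the precision; RMA values of very bright or dim probe sets understate fold changes.

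Of the 33297 probe sets in the table, 19460 had 1 gene symbol in the platform annotation given, 1754 had several and 12083 had no gene named there. Only probe sets with 1 gene symbol were named. Symbols were updated through their gene IDs with a RefSeq gene table, which held 19429 of the 19460. No coordinates are reported, because the build of the array annotation is not given in the sources used here. For the 769 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which gave 18417 genes. Genes below the 30th percentile of mean log2 value, here 6.03, were left out, and 12905 genes were tested. This mean ran over all arrays, so a gene low with siControl could pass through its siChe-1 values. Counts among tested list members can therefore favour genes that rose.

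A linear model with the 4 groups as cell means was fitted to all 10 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. It had 6 residual degrees of freedom and 4.92 prior degrees of freedom. The contrasts were siChe-1 minus siControl in SKBR3, the same in MDA-468, the mean of these changes with equal weight per line, and the SKBR3 change minus the MDA-468 change. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05, and a gene past it is called changed. Values of groups are means ± SD of log2 values, fold changes are log2 values with the standard error (SE) of the fit, and the AATF interval is a 95% confidence interval. Genes called in both lines were counted per direction, beside the number that independent calls would share and, where given, Fisher's exact test (2-sided).

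Before the data were examined, 21 pathway lists and 6 lists of cell type markers were written down, together with the tests, the alternatives and the rule for genes to be named. Pathway lists were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the 21 lists of a comparison. The same test with a correlation estimated from the residuals, and fry, were alternatives. Camera compares a list with the other genes; fry asks whether the genes of a list move, on balance, in a single direction. The genes to be named were a panel of 6, of which 4 were analysed here (AATF, TP73, CDKN1A and MDM2), and the 10 highest and 10 lowest fold changes of SKBR3, MDA-468 and both lines together. These were taken among called genes whose siChe-1 arrays all lay on the same side of all siControl arrays of the line. The rule also took the 5 highest and 5 lowest values of the difference between lines, up to 3 members of each list with the smallest p, and members behind a count of 5 or fewer. Members named beyond these were chosen after their values were seen. Camera was also run on the 4 marker lists with at least 3 tested genes, adjusted over those 4 lists; this test was added after the data were seen.

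The alternatives were no filter, a filter at the 50th percentile, each line fitted alone, the replicate number as a block, quantile normalization of the deposited values again, centring of each array on its median, eBayes with an intensity trend and robust prior, array weights, the probe set with the lowest mean, a 1.5-fold threshold, and leaving out each array in turn. Array weights were fitted with a convergence warning. The analysis was checked on simulated data in which known genes were changed among 12905. For SKBR3, 50.7% of genes changed by 0.5 on the log2 scale, 97% of those changed by 1 and 100% of those changed by 2 were called; for MDA-468 these shares were 65.7%, 98.5% and 100%. False calls made up 4.62% of the simulated SKBR3 calls and 7.37% of the simulated MDA-468 calls. The simulated noise was independent between genes and had the same spread in all groups. The real replicates deviated along a shared axis. The SD of the difference between replicates was 0.404 in SKBR3 siChe-1 and 0.338 or less in the other groups. These shares may therefore not hold for the real arrays, above all in SKBR3. Figures were drawn with Python 3.11.15.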

Results

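The response to a duplex against Che-1 was measured in SKBR3, a breast cancer line with high ERBB2, and in MDA-468, a basal-like line with high EGFR. Che-1, encoded by AATF, is a nuclear protein that binds RNA polymerase II and takes part in transcription, the DNA damage response and ribosome assembly. Expression was measured 48 h after transfection of a control or an AATF-directed duplex, on 4 SKBR3 and 6 MDA-468 arrays. The labels name 1 reagent against AATF. For none of the changes below can a response to AATF loss therefore be told apart from a response to the duplex itself. Replicate arrays correlated with r = 0.992 in SKBR3 siControl (n = 2), 0.978 in SKBR3 siChe-1 (n = 2), 0.995 to 0.996 in MDA-468 siControl (n = 3) and 0.990 to 0.995 in MDA-468 siChe-1 (n = 3), over the 12905 genes tested. No pair of arrays held the same values.

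AATF was lower on every siChe-1 array than on every siControl array of its line. In SKBR3 its log2 value was 8.69 ± 0.006 (SD, n = 2) with siControl and 8.03 ± 0.083 (SD, n = 2) with siChe-1, a fall of 0.66 on the log2 scale (95% interval -0.87 to -0.45, limma adjusted p = 0.000779). In MDA-468 it was 8.88 ± 0.024 (SD, n = 3) with siControl and 7.17 ± 0.11 (SD, n = 3) with siChe-1, a change of -1.71 (95% interval -1.88 to -1.54, adjusted p = 2.16e-08). AATF signal thus stood at 63.3% of control in SKBR3 and 30.5% in MDA-468, and the fall was 1.05 log2 units deeper in MDA-468 (adjusted p = 0.000216). In SKBR3, 434 called genes fell further than AATF itself, and in MDA-468 35 did.

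**Figure D1:**
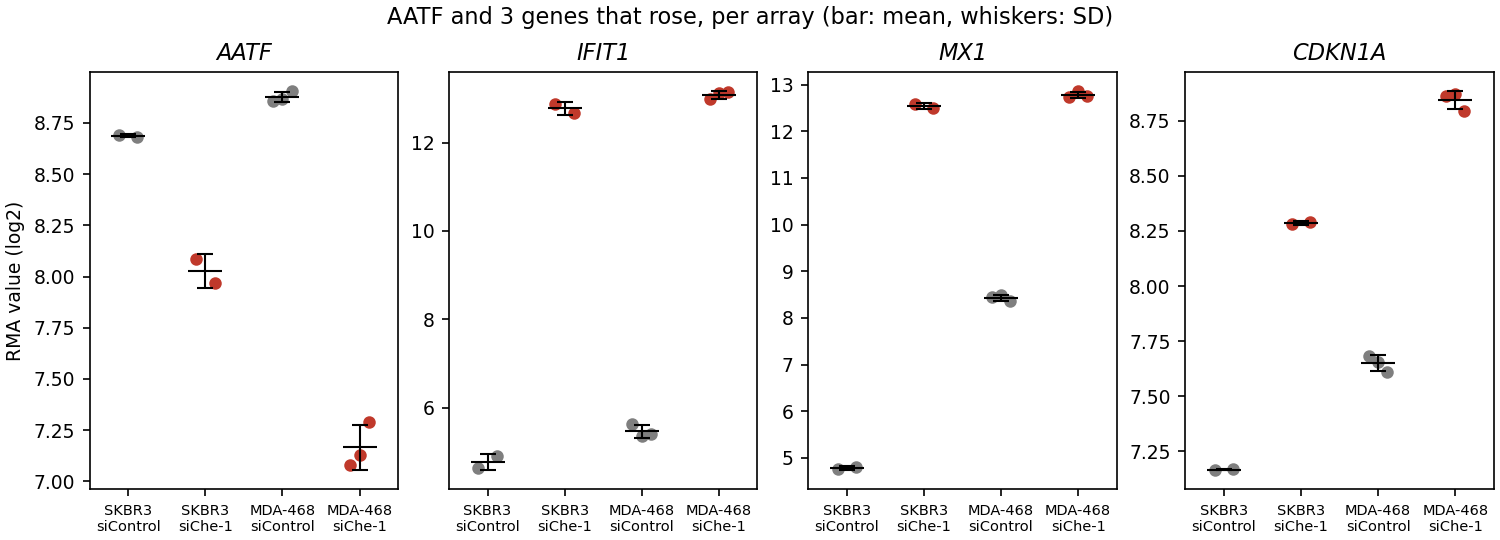
RMA values (log2, vertical axes that do not start at 0) of AATF, IFIT1, MX1 and CDKN1A on each of the 10 arrays (points) with the mean and SD of each group (bars and whiskers). AATF is lower and the other 3 genes are higher on every siChe-1 array than on any siControl array of the same line.

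In SKBR3, antiviral genes rose by up to 8.36 log2 units with siChe-1, and 31 of 34 genes of the G2/M and mitosis list fell, although the list's call was lost (adjusted p = 0.261 with an estimated correlation). The 10 largest rises were those of IFIT2 (8.36 ± 0.17, log2 fold change ± SE), IFIT1 (8.01 ± 0.13), IFI44 (7.82 ± 0.11), MX1 (7.75 ± 0.09), HERC5, PARP14, IFIT3, CXCL10, DDX60L and IFITM1, the last at 6.54 ± 0.11. IFIT proteins bind viral RNA, MX1 is an antiviral GTPase and CXCL10 is a chemokine induced by interferon. The largest falls were smaller: ATPSCKMT fell by 1.64 ± 0.17, ATL3, which shapes endoplasmic reticulum tubules, by 1.56 ± 0.17, SLC9A2 by 1.54 ± 0.17 and DEPDC1 by 1.52 ± 0.23. CEP20, FUT9, NUF2, GET1, REEP1 and PRR11 followed, PRR11 with a fall of 1.28 ± 0.15. CDKN1A, the cell cycle inhibitor p21, rose by 1.12 ± 0.08 (adjusted p = 2.62e-06), whereas TP73 (0.25, adjusted p = 0.264) and MDM2 (-0.28, adjusted p = 0.119) did not pass the test.

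Of the 12905 genes tested, 3054 were called in SKBR3, 856 higher and 2198 lower. Rises were larger than falls: 125 genes rose and 0 fell by more than 4-fold. At an unadjusted p below 0.05, 4699 genes passed. The number of calls was 669, 437 of them higher, when SKBR3 was fitted alone, so the count depended on the spread that the fit shares between the lines. This spread can be too small for SKBR3. The SD of the difference between its siChe-1 replicates was 0.404, against 0.338 or less in the other groups. The SEs and p-values of SKBR3 can then be too small as well. The count also moved when single SKBR3 arrays were left out, which leaves a group without a replicate.

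All 31 tested interferon-stimulated genes rose in SKBR3, over all genes tested and adjusted over the list alone, by 2.04 (IRF7) to 8.36 (IFIT2) log2 units with a median of 5.65 (camera adjusted p = 5.78e-76). OAS1, a sensor of double-stranded RNA, rose by 6.47. NF-kappaB targets and cytokines rose in 15 of 18 (16 adjusted over the list alone; camera adjusted p = 8.87e-17), with TNFAIP3 at 2.82 ± 0.11, IL6 at 2.61 ± 0.16 and NFKBIA at 1.30 ± 0.09. Immediate early genes rose in 17 of 21 (18 adjusted over the list alone; camera adjusted p = 4.52e-18), among them KLF4 at 2.09, JUN at 2.06 and CCN1 at 1.69. These 3 calls held with an estimated correlation, with adjusted p = 0.00106 for the first list, 0.00106 for the second and 0.00738 for immediate early genes. Of 25 listed NF-kappaB targets and cytokines, 18 passed the filter, some through their siChe-1 values. IL6, for example, stood at 5.21 with siControl in both lines, below the filter level of 6.03. With no filter, counted after the data were seen, 31 of 32 interferon-stimulated genes with a probe set rose in SKBR3 and 32 in MDA-468.

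G2/M and mitosis genes fell in 31 of 34 in SKBR3 (32 adjusted over the list alone; camera adjusted p = 6.51e-13), with ASPM at -1.12 ± 0.13, CENPF at -1.08 ± 0.11 and KIF20A at -0.89 ± 0.11. The call was lost with an estimated correlation, at an adjusted p = 0.261. Mesenchymal and matrix genes shifted up (camera adjusted p = 0.00156, adjusted p = 0.129 with an estimated correlation) through 4 of 15: FN1 (1.87), PLAUR (1.78), SNAI1 (1.35) and ITGA5 (0.41), the same 4 adjusted over the list alone. Pro-apoptotic factors shifted up too (camera adjusted p = 0.0118, adjusted p = 0.129 with an estimated correlation), although their median was -0.04 and their mean 0.33. Of 20 measured, 7 rose and 1 fell, also adjusted over the list alone; PMAIP1, which encodes the BH3 protein NOXA, rose by 3.71 ± 0.15 and the death receptor gene TNFRSF10B by 0.93, while APAF1, the core of the apoptosome, fell by 0.71.

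The other 15 pathway lists did not pass camera in SKBR3, with adjusted p from 0.111 to 0.961. Of 31 p53 target genes, 8 rose and 5 fell, with CDKN1A and PMAIP1 among the first and CCNG1, ZMAT3, RRM2B, CYFIP2 and APAF1 the second (median -0.05, mean 0.16, camera adjusted p = 0.111). ATF4 and amino acid response genes rose in 6 and fell in 8 of 29, with PPP1R15A at 3.55, NUPR1 at 2.05 and ATF3 at 1.84 on the rising side. DNA damage checkpoint and repair genes rose in 4 of 27 (CHEK2 at 1.05, RAD9A, RAD54L and NBN) and fell in 10. Of 42 measured G1/S and replication genes, 9 fell and none rose. WDR12, DCAF13, HEATR1 and RRN3 fell among 42 ribosome biogenesis factors, RPL23 and RPL11 among 37 ribosomal proteins, and SDHD, NDUFS1, NDUFB5 and SDHC among 32 oxidative phosphorylation genes. All of these except RRN3 and SDHC, which were not followed through the alternatives, lost the threshold under at least 1 alternative. Adjusted over the list alone, the counts were 8 higher and 5 lower for p53 targets, 6 and 10 for the ATF4 list, 4 and 14 for DNA repair, 7 lower for G1/S, 1 lower for ribosome biogenesis, 0 for ribosomal proteins and 4 lower for oxidative phosphorylation.

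Among hypoxia response genes 5 of 23 rose in SKBR3 (ADM at 1.61, VEGFA, HK2, ANKRD37 and PFKFB3) and 3 fell (SLC2A1, NDRG1 and BNIP3L), with 6 and 6 adjusted over the list alone. DDIT4 and GABARAPL1 rose and DEPTOR, GABARAP, ATG16L1, BECN1 and GABARAPL2 fell among 25 autophagy and mTOR inhibitor genes. STARD4 rose and CYP51A1, DHCR7, ACAT2 and MVK fell among 19 cholesterol synthesis genes. HBEGF, BTC and EGFR rose among 7 ERBB receptors and ligands, H2BC21, H3C10 and H4C14 among 21 histones, XBP1 and SDF2L1 among 21 endoplasmic reticulum genes, DNAJA1 among 13 heat shock genes, and MCL1 rose and BIRC5 fell among 7 anti-apoptotic factors. Adjusted over the list alone, these counts were unchanged except for cholesterol synthesis, with 5 lower, for ERBB genes, with 2 lower besides, and for the endoplasmic reticulum list, with 0.

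In MDA-468 antiviral genes rose as well, and 20 genes fell by more than 4-fold. The 10 largest rises were those of IFIT2 (7.62 ± 0.14), IFIT1 (7.61 ± 0.11), IFI44L (7.51 ± 0.13), RSAD2 (7.27 ± 0.14), CCL5 (6.76 ± 0.09), CXCL10, OASL, IFI6, OAS2 and SAMD9L, the last at 5.40 ± 0.13. The 10 deepest falls were those of CYP4Z2P (-3.49 ± 0.11), AKR1C1 (-3.14 ± 0.08), CYP4Z1 (-2.97 ± 0.08), AKR1C3 (-2.95 ± 0.12), CRISP3 (-2.78 ± 0.11), AKR1C2, PTGS1, CLCA2, FMO6P and AK5, the last at -2.34 ± 0.09. AKR1C enzymes reduce steroids and prostaglandins and PTGS1 is cyclooxygenase 1. AKR1C1, AKR1C2 and AKR1C3, and CYP4Z1 and its pseudogene CYP4Z2P, are near-identical in sequence, so their probe sets may read each other's transcripts and the single members are uncertain. CDKN1A rose by 1.20 ± 0.07 (adjusted p = 1.33e-07), whereas TP73 (-0.01, adjusted p = 0.94) and MDM2 (0.01, adjusted p = 0.932) did not pass the test.

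In MDA-468 5600 genes were called, 2118 higher and 3482 lower, and 132 rose and 20 fell by more than 4-fold. At an unadjusted p below 0.05, 6430 passed. With a 1.5-fold threshold 2100 remained past both thresholds, 895 higher and 1205 lower, so most calls were small changes.

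All 31 interferon-stimulated genes rose in MDA-468 as well, also adjusted over the list alone, by 1.31 (IRF7) to 7.62 (IFIT2) with a median of 4.59 (camera adjusted p = 5.65e-40; adjusted p = 0.0064 with an estimated correlation). XAF1 rose by 4.98. NF-kappaB targets and cytokines rose in 15 of 18, the same count adjusted over the list alone, with IL6 at 5.19 ± 0.13, TNFAIP3 at 4.04 ± 0.09 and TNFAIP2 at 1.45 ± 0.07 (camera adjusted p = 9.84e-12; adjusted p = 0.0054 with an estimated correlation). Immediate early genes rose in 19 of 21, among them KLF4 at 3.38, JUN at 2.29 and KLF6 at 1.95, and BTG1 fell by 0.27 (same counts adjusted over the list alone; camera adjusted p = 8.27e-13; adjusted p = 0.0183 with an estimated correlation).

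G2/M and mitosis genes fell in 26 of 34 in MDA-468, the same count adjusted over the list alone, among them KIF20A (-1.14), CCNB2 (-1.11) and PLK1 (-0.85), with a camera adjusted p = 4.46e-07 and an adjusted p = 0.335 with an estimated correlation. Ribosomal proteins fell in 33 of 37 (35 adjusted over the list alone; median -0.41), with RPL23 at -0.94, RPL7 at -0.63 and RPS6 at -0.55 (camera adjusted p = 4.69e-08; adjusted p = 0.221 with an estimated correlation). Oxidative phosphorylation genes fell in 30 of 32 (30 adjusted over the list alone; median -0.43), with NDUFB10 at -0.90, ATP5PB at -0.90 and NDUFB8 at -0.71 (camera adjusted p = 6.1e-08; adjusted p = 0.221 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 19 (15 adjusted over the list alone; median -0.74), among them PMVK, with INSIG1 at -1.14 and FDPS at -0.88, while STARD4 rose by 0.89, as 1 of 2 genes higher adjusted over the list alone (camera adjusted p = 6.03e-05; adjusted p = 0.334 with an estimated correlation). The medians of these 4 lists stayed below 0 when the arrays were quantile-normalized again or centred on their medians, and the calls held after quantile normalization; centring leaves camera's comparison with other genes nearly as it was.

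ATF4 and amino acid response genes rose in 17 and fell in 5 of 29 in MDA-468 (17 and 6 adjusted over the list alone; camera adjusted p = 0.000607; adjusted p = 0.262 with an estimated correlation). ATF3 rose by 3.18, WARS1 by 2.54 and PPP1R15A by 2.03; the serine synthesis gene PHGDH fell by 0.67, and MTHFD2, SHMT2, PSPH and ATF4 itself fell by 0.41 or less. Mesenchymal and matrix genes rose in 9 of 15, with ITGA5 at 3.01, FN1 at 2.35 and PLAUR at 1.88, and TIMP1 fell by 0.99 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000191; adjusted p = 0.106 with an estimated correlation). ERBB receptors and ligands rose in 5 of 7 (BTC at 0.95, EGFR at 0.72, HBEGF at 0.64, EGF and TGFA) and ERBB2 fell by 0.29 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0159, but 0.273 with a filter at the 50th percentile; adjusted p = 0.221 with an estimated correlation). In all, 10 of 21 lists were called with the preset correlation and 3 with an estimated one. The 9 other ways to split the 6 arrays 3 against 3 gave 7 to 12 lists with the preset correlation and 0 with an estimated one. Each of these splits mixes the groups, so part of the siChe-1 changes stays in its contrast. The rest enters the spread and the estimated correlation. Neither count therefore shows how many lists would be called without a siChe-1 response.

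The remaining 11 lists did not pass camera in MDA-468, with adjusted p from 0.0529 to 0.729. Among 31 p53 target genes 11 rose, among them PMAIP1 at 2.84, GADD45A at 1.90 and CDKN1A, and 10 fell (median -0.03, mean 0.22, camera adjusted p = 0.301). Pro-apoptotic factors rose in 7 of 20, with FAS at 3.06 and TNFRSF10B at 1.25, and CASP9, HTRA2, APAF1 and CYCS fell. MCL1, BIRC2 and BCL2L1 rose and BIRC5 and XIAP fell among 7 anti-apoptotic factors. CHEK2 rose by 1.36 among 7 risen and 6 fallen of 27 DNA repair genes, with XRCC5 at -0.67 and PRKDC at -0.62 among the latter. Of 42 G1/S genes 14 fell, UNG by 0.70, and CDC25A, ORC6, CHAF1A, POLA2 and POLE rose; of 42 ribosome biogenesis factors 16 fell, DCAF13 by 0.85 and WDR12 by 0.83, and BMS1 rose. Histones rose in 7 of 21, with H4C8 at 1.92, and H1-1, H1-5 and H3C2 fell. XBP1, DNAJB9, HSPA5 and DNAJB11 rose and SEC61B and HERPUD1 fell among 21 endoplasmic reticulum genes; DNAJA1 rose and HSPE1, HSP90AA1 and DNAJB1 fell among 13 heat shock genes. DDIT4, ULK2, GABARAPL1 and ATG2A rose among 25 autophagy and mTOR inhibitor genes and 7 fell, with DEPTOR at -1.58; 6 of 23 hypoxia response genes rose, with ADM at 1.51, and BNIP3L, PGK1, LDHA, SLC2A1 and P4HA1 fell. Adjusted over the list alone, the counts of these lists were the same except for 7 lower among DNA repair genes, 6 higher among G1/S genes and 5 higher among autophagy genes.

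**Figure D2:**
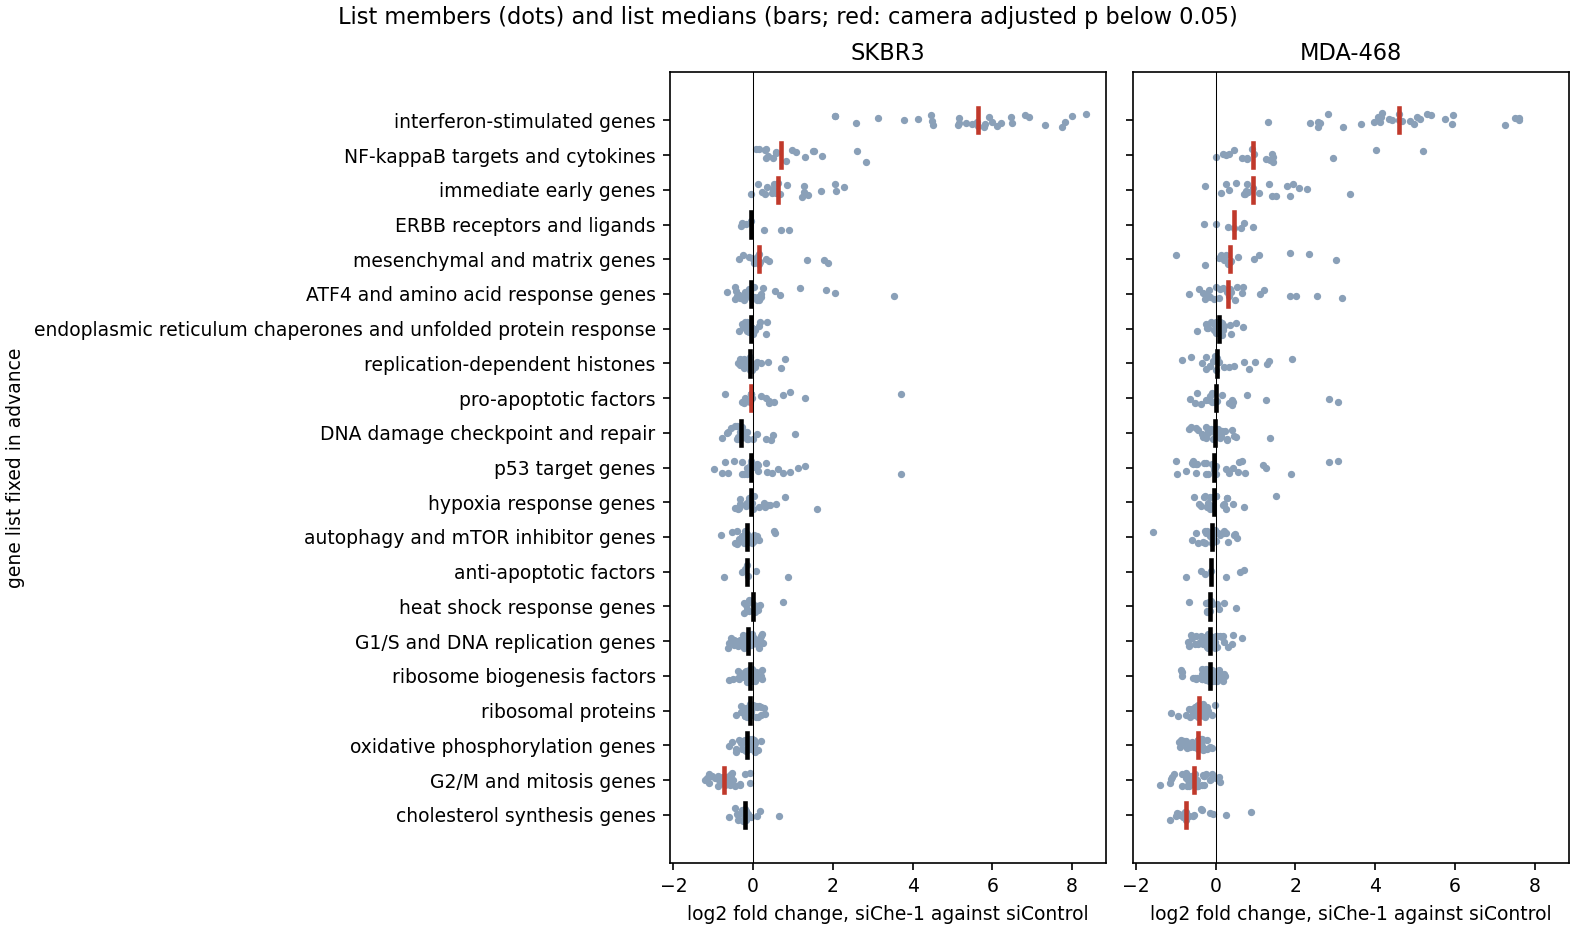
Log2 fold changes (siChe-1 against siControl) of the members of the 21 pathway lists (dots) and the list medians (bars, red where the camera adjusted p is below 0.05) in SKBR3 and MDA-468. Interferon-stimulated genes have medians of 5.65 and 4.59, and all other list medians lie between -0.74 and 0.95.

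Across both lines, 626 genes were called higher in each and 1198 lower in each. Independent calls would share 140.5 and 593.1. For the lower genes Fisher's exact test gave p = 3.48e-202, with genes that are not independent replicates. Both lines also take the same spread per gene from the fit, which can link their calls. Another 30 genes were higher in SKBR3 and lower in MDA-468, and 147 were lower in SKBR3 and higher in MDA-468. Independent calls would give 231 and 360.7 of these. Across genes the fold changes of the lines correlated with Pearson's r = 0.679 and Spearman's rho = 0.475, and with r = 0.61 and rho = 0.471 without the interferon-stimulated list. The number of shared calls, 1824, fell to 577 when each line was fitted alone and to 929 without SKBR3 siControl replicate 2, and the balance turned, with 391 higher and 186 lower in the first case and 482 and 447 in the second.

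Averaged over the lines, 5791 genes were called, 1763 higher and 4028 lower, and 6637 passed at an unadjusted p below 0.05. The highest were IFIT2 (7.99 ± 0.11), IFIT1 (7.81 ± 0.08), RSAD2, CXCL10, CCL5, IFI44, HERC5, IFIT3, MX1 and IFI44L (5.99 ± 0.10). Among called genes whose siChe-1 and siControl arrays did not overlap in either line, the lowest were CYP4Z2P (-2.23 ± 0.09), CRISP3 (-1.84 ± 0.09), CYP4Z1, ATPSCKMT (-1.75 ± 0.11), GET1, NT5DC2, PRR11, AGR2, CLCA2 and REEP1 (-1.46 ± 0.14). AGR2 encodes a disulfide isomerase of secretory epithelium and GET1 a receptor for tail-anchored proteins. AATF averaged -1.19 ± 0.06 and CDKN1A 1.16 ± 0.05, whereas TP73 (adjusted p = 0.354) and MDM2 (adjusted p = 0.191) did not pass.

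**Figure D3:**
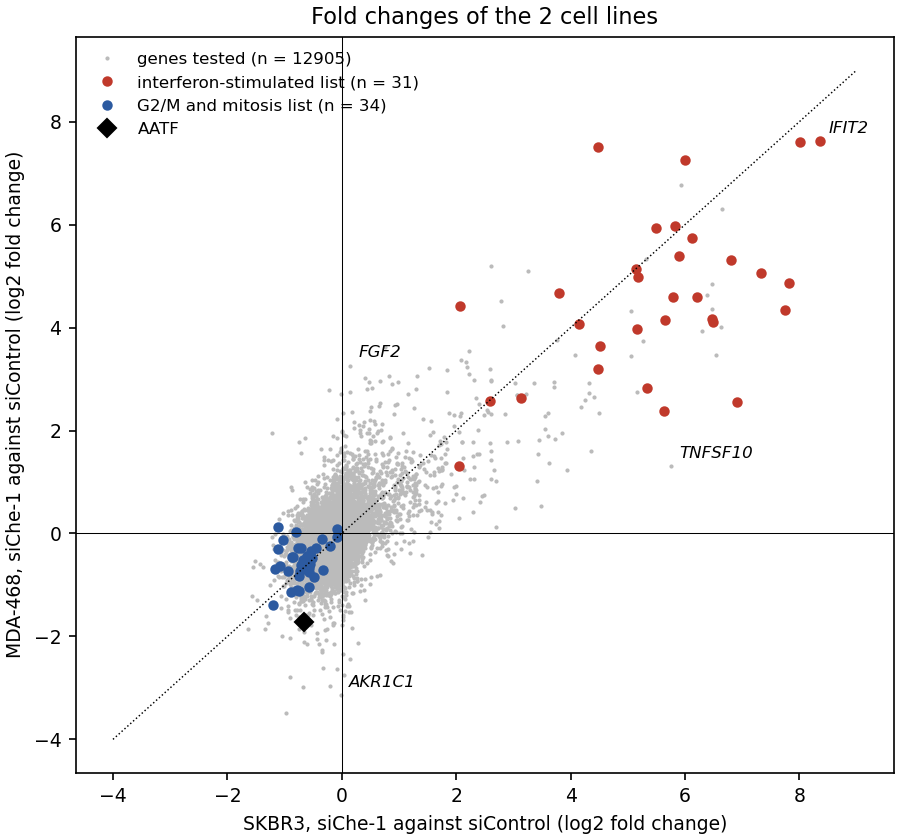
Log2 fold changes of the 12905 genes tested in SKBR3 (horizontal axis) and MDA-468 (vertical axis), with 31 interferon-stimulated genes in red, 34 G2/M and mitosis genes in blue, AATF as a diamond and a dotted line of equal change. All interferon-stimulated genes lie above 1.3 in both lines; TNFSF10 and AKR1C1 are far from the line of equal change.

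The response differed between the lines for 2466 genes, with the SKBR3 change above the MDA-468 change in 1092 and below it in 1374; 4127 passed at an unadjusted p below 0.05. TNFSF10, the death ligand TRAIL, rose by 5.75 in SKBR3 and 1.30 in MDA-468, a difference of 4.45 ± 0.16 (adjusted p = 1.44e-07). PARP14 (4.35 ± 0.18), MX1 (3.40 ± 0.12) and PARP9 (3.25 ± 0.16) also rose further in SKBR3. The SKBR3 siControl levels of TNFSF10, PARP14, MX1 and PARP9 were 3.90, 4.52, 4.79 and 4.23, below the filter level of 6.03. In MDA-468 they were 10.91, 9.52, 8.43 and 9.03, which left less room to rise. The sizes of these differences therefore do not rank the strength of the response. AKR1C1 (3.12 ± 0.12) fell in MDA-468 from a siControl level of 12.01, but its siControl level in SKBR3, 5.83, lay below the filter level of 6.03 and left little room to fall, so this value does not compare responses; it was also not called with the probe set of lowest mean. Of 849 called differences with a fall in MDA-468, 135 had such a siControl level in SKBR3, and of 484 with a fall in SKBR3, 17 had one in MDA-468. In the other direction stood GASK1B (-3.18 ± 0.23), the growth factor gene FGF2 (-3.12 ± 0.15), IFI44L (-3.03 ± 0.20), ANKRD1 (-3.01 ± 0.18) and IL7R (-2.86 ± 0.20). In SKBR3, FGF2, ANKRD1 and IL7R had siControl levels of 5.29, 4.73 and 3.90 and stayed below the filter level with siChe-1. GASK1B and IFI44L stood at 4.71 and 5.24 in MDA-468 siControl, also below it. These sizes therefore do not rank responses either. The count was 1523 with each line fitted alone, 1520 without SKBR3 siControl replicate 2 and 4069 without SKBR3 siChe-1 replicate 1.

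Camera called 4 lists for the difference, and 0 with an estimated correlation. Interferon-stimulated genes rose further in SKBR3 in 17 of 31 and further in MDA-468 in 5 (IFI44L, CMPK2, RSAD2, IFI6 and IFI27), with a median difference of 0.74 (camera adjusted p = 1.08e-08; adjusted p = 0.496 with an estimated correlation). Ribosomal proteins lay higher in the SKBR3 response in 10 of 37 (camera adjusted p = 2.85e-08; adjusted p = 0.497 with an estimated correlation), cholesterol synthesis genes in 11 of 19 (camera adjusted p = 0.000213; adjusted p = 0.548 with an estimated correlation) and oxidative phosphorylation genes in 12 of 32 (camera adjusted p = 6.58e-05; adjusted p = 0.548 with an estimated correlation). Adjusted over the list alone these counts were 20 and 5, 17, 12 and 13. Of lists that camera did not call (adjusted p from 0.0717 to 0.164), NF-kappaB targets had 3 genes with the higher change in SKBR3 and 8 in MDA-468, among them IL6 (-2.58), LIF (-1.97) and TNFAIP2 (-0.96); mesenchymal genes had 2 and 5, with ITGA5 (-2.60), and immediate early genes 3 and 5, with KLF10 (-1.79) and KLF6 (-1.48). ATF4 and amino acid response genes had 4 and 10, with NUPR1 (1.76) and PPP1R15A (1.52) among the first and CTH (-2.51), WARS1 (-1.87) and ATF3 (-1.34) among the second. Adjusted over the list alone these counts were 3 and 8, 2 and 6, 3 and 7, and 4 and 12. Camera called 7 lists for the difference without either SKBR3 siChe-1 array.

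The camera tests of these marker lists were added after the data were seen. In MDA-468, 7 of 9 measured basal markers rose, with KRT14 at 1.95, CDH3 at 1.24, VIM at 1.10 and KRT5 at 0.82, and CD44 fell by 0.23 (camera adjusted p = 0.00038; adjusted p = 0.0891 with an estimated correlation). Of 11 tested luminal markers 5 fell there, SPDEF (-1.67), FOXA1 (-0.73), MUC1 (-0.61), ERBB2 and KRT19, and KRT7 and KRT18 rose (camera adjusted p = 0.233). In SKBR3, CAV1 and EGFR rose among the basal markers (camera adjusted p = 0.0138; adjusted p = 0.157 with an estimated correlation) and none of 11 luminal markers was called (camera adjusted p = 0.517). Of the leukocyte markers, CD68 (1.49) and CD14 (0.53) rose in SKBR3 and ITGAM (1.07), CD14 (0.64) and CD68 (0.46) in MDA-468, with a camera adjusted p = 0.0138 and 0.0265, and an adjusted p = 0.157 and 0.161 with an estimated correlation. PTPRC, the pan-leukocyte gene, stood at 3.25 and 3.29 with siControl and siChe-1 in SKBR3 and at 4.03 and 3.69 in MDA-468, both below the filter. Fibroblast genes gave camera adjusted p = 0.517 and 0.233, with COL1A1 risen by 0.34 in MDA-468; the only tested adipocyte gene, PLIN1, was not called, and the 5 endothelial genes lay below the filter.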

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

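The tests of leukocyte RNA, of the duplex and of the axis of replicate deviations, and the splits counted with an estimated correlation, were chosen after the results were seen.

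The siChe-1 response differed between the lines, by the test of the difference itself, for 2466 genes. Among genes named in the report, the SKBR3 change minus the MDA-468 change was 4.45 for TNFSF10, 4.35 for PARP14, 3.40 for MX1, 3.25 for PARP9, 3.08 for IFITM1, 2.95 for IFI44, 2.61 for DDX60L, 2.28 for HERC5, 1.51 for IFIT3 and 0.74 for IFIT2, all of which rose in both lines. It was -0.44 for IFI6, -0.83 for CCL5, -1.26 for RSAD2 and -3.03 for IFI44L, which also rose in both. The genes listed with the larger rise in SKBR3 had siControl means there from 3.27 (IFI44) to 4.96 (IFITM1), below the filter level of 6.03. Their MDA-468 siControl means ran from 5.46 (IFIT2) to 10.91 (TNFSF10), so these differences may depend on the starting level. CCL5 and RSAD2, which rose further in MDA-468, stood at 5.50 and 4.52 in SKBR3 siControl, also below that level. Genes whose change lay lower in MDA-468 gave 3.12 for AKR1C1, 2.80 for AKR1C2, 2.75 for AKR1C3, 2.57 for FMO6P, 2.56 for PTGS1, 2.51 for CYP4Z2P, 2.36 for AK5, 2.29 for CYP4Z1, 2.28 for CLCA2, 1.88 for CRISP3, 1.14 for AGR2, 1.05 for AATF and 0.96 for NT5DC2. Of these, AKR1C1, AKR1C3, FMO6P, PTGS1 and AK5 had siControl means of 5.83, 4.56, 4.17, 5.75 and 3.48 in SKBR3, below the filter level of 6.03, which left little room to fall there, so their differences do not compare responses; AKR1C2, CYP4Z2P and CLCA2, at 6.32, 6.32 and 6.21, lay just above it. Genes that fell deeper in SKBR3 gave -0.84 for FUT9, -0.90 for SLC9A2, whose siControl mean in MDA-468 was 5.97, and -0.99 for DEPDC1. IL7R (-2.86), ANKRD1 (-3.01) and FGF2 (-3.12) rose in MDA-468 with changes of 0.76, -0.23 and 0.14 in SKBR3, and GASK1B (-3.18) rose by 1.96 in MDA-468 and fell by 1.22 in SKBR3. IL7R, ANKRD1 and FGF2 lay below the filter level of 6.03 in both SKBR3 groups, where fold changes can be understated. GASK1B stood at 4.71 in MDA-468 siControl, which left little room to fall there. Of the list members that the naming rule took, another 62 differed too, 29 with the larger value in SKBR3 and 33 with the smaller, from 2.30 for OAS1 to -2.60 for ITGA5. List members that the rule did not take are not in this count. The lists with a called difference had median differences of 0.32 (ribosomal proteins), 0.74 (interferon-stimulated genes), 0.50 (cholesterol synthesis) and 0.32 (oxidative phosphorylation), and all 4 calls were lost with an estimated correlation, at adjusted p = 0.497, 0.496, 0.548 and 0.548 in that order.

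Probe sets outside the gene comparisons also carried signal above the siControl arrays. Of 12083 probe sets with no gene named here, 42 were called over 2-fold higher with siChe-1 in both lines and 0 over 2-fold lower in both, and of 1754 with several genes, 10 were higher and 0 lower by the same limma test over all 33297 probe sets.

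Interferon-stimulated genes rose by medians of 5.65 and 4.59 in the siChe-1 arrays of both lines. RNA of leukocytes in those cultures would bring their abundant transcripts, but the median change over 7 leukocyte genes was 0.182 in SKBR3 and 0.163 in MDA-468, and PTPRC changed by 0.05 and -0.33, against this explanation; CD14, CD68 and ITGAM, which rose, can be made by other cells as well. A response to the transfected duplex rather than to AATF loss cannot be told apart from a response to AATF loss, because the labels name 1 reagent against AATF and the control duplex differs from it in sequence. Arrays with another AATF duplex, or with AATF restored, were not analysed here.

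Interferon-stimulated genes rose further in SKBR3, by a median of 0.74 log2 units (limma's fry, adjusted p = 0.000197, and camera, adjusted p = 0.496 with an estimated correlation), although AATF fell less there. Starting levels differed, however. MX1 went from 4.79 to 12.53 in SKBR3 and from 8.43 to 12.78 in MDA-468. PARP14 went from 4.52 to 11.44 and from 9.52 to 12.08. IFI44L, which rose further in MDA-468, went from 7.51 to 11.99 in SKBR3 and from 5.24 to 12.75 in MDA-468. The larger rise in SKBR3 does not by itself show a stronger response there. Fry called 9 lists for the difference, and the order of the lines was not the same in all of them. NF-kappaB targets and cytokines (adjusted p = 0.000197), immediate early genes (0.00524), mesenchymal and matrix genes (0.0103), and the ATF4 and ERBB lists (0.0252 for each) had the higher change in MDA-468. Ribosomal protein (0.00524), oxidative phosphorylation (0.0232) and cholesterol synthesis genes (0.0252) had it in SKBR3, since they fell further in MDA-468. No test run here decides between the depth of AATF loss and other differences between the lines, which stay open.

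Ribosomal protein and oxidative phosphorylation genes fell in MDA-468 with medians of -0.407 and -0.432. Both lists are bright, but 10000 random lists matched on mean level had medians of -0.166 and -0.153, with central 95% ranges of -0.286 to -0.0698 and -0.298 to -0.0129. Matched genes thus fell less than both lists, and a shift of all bright probe sets may account for part of the falls. The random lists drew genes singly, without the correlation within the real lists, estimated at 0.189 and 0.255. Their ranges can therefore be too narrow to decide whether such a shift is the whole cause. Replicate arrays deviated along a shared axis that held 62% of the within-group variance, but its correlation with the MDA-468 fold changes was 0.071 across genes, so that removing it moved little (medians of -0.417 and -0.439) and decides nothing. A biological response, and technical differences between siControl and siChe-1 arrays, along this axis or not, stay open, and the lists lose their calls with an estimated correlation. The axis correlated more with the SKBR3 fold changes (0.222) and with the differences between lines (0.177). The SKBR3 siChe-1 arrays lay furthest apart on it, at -17.94 and 17.94. Its part in the SKBR3 changes and in the differences was not tested.

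Other splits of the arrays were counted for MDA-468 and, within each line, for both lines together, where SKBR3 has 2 arrays a group. For MDA-468 alone there are 10 splits, too few for a share under 0.05: the real split called 5600 genes, 1 of the 10 splits reached that count, and the highest other split called 0. For gene lists in MDA-468 the real split called 10 and the highest other 12, and 5 of the 10 splits called as many as the real one; with an estimated correlation the real split called 3 and all 9 others 0, a check added once the first count was known. Splitting both lines at the same time gives 60 splits. For both lines together 1 of them, the real one, reached 5791 genes, and the highest other called 2514; for shared calls the real split gave 1824 and the highest other 177. No other split reached the last 2 counts, of both lines together and of shared calls. Splits that mix siChe-1 with siControl arrays keep part of the siChe-1 changes in the contrast and put the rest into the spread. This lowers their gene counts and can lower their list counts with an estimated correlation. Their list counts with the preset correlation, 7 to 12, were not lowered throughout. The comparison therefore does not exclude chance, or a technical difference between the transfections.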

How the results depend on the processing

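The crossed block and the counts without the interferon-stimulated list were chosen after seeing the data. So were the counts of interferon genes and of interferon-stimulated genes without the filter. All other alternatives were planned. AATF kept its direction and its threshold in both lines under all alternatives run. Of 236 named results past the threshold, 189 kept direction and threshold under every alternative applied to them and 47 lost the threshold under at least 1. The 1.5-fold threshold was applied to counts of genes only, not to AATF or the named results. Some named results past the adjusted p threshold, such as RPS6 in MDA-468 (-0.55), changed by less than 1.5-fold. Among results not past the adjusted p threshold, 5 changed sign somewhere. For counts that moved by over 1.5 times, the cause was not tested beyond the alternatives themselves. With each line fitted alone, SKBR3 had 669 calls (437 higher, 232 lower, against 856 and 2198), the difference 1523 and shared calls 577; list tests of the difference were not run for this setting. With array weights SKBR3 had 1170 calls and shared calls numbered 926. With a 1.5-fold threshold there were 1191 calls in SKBR3, 2100 in MDA-468, 1255 in both lines together, 1597 for the difference and 577 shared, fewer by construction. Shared calls were mostly lower (1198 of 1824) but mostly higher with each line fitted alone (391), the replicate block (457), the 1.5-fold threshold (341) and without SKBR3 siControl replicate 2 (482). With an estimated correlation camera called 3 lists in SKBR3, 3 in MDA-468 and 0 for the difference; fry called 9 for the difference, 4 with the higher change in SKBR3 and 5 in MDA-468. Scaling moved the share of higher calls by less than 10 percentage points: 28.0% in SKBR3 became 30.3% after quantile normalization and 24.5% after centring, and 37.8% in MDA-468 became 41.6% and 33.1%.

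Leaving out each array gave 1281 (without SKBR3 siControl replicate 2) to 5353 calls (without SKBR3 siChe-1 replicate 1) in SKBR3, 4522 to 6566 in MDA-468, 4917 to 7350 in both lines together, 1520 to 4069 for the difference and 929 to 2732 shared, the lowest and highest of the last 3 without the same 2 SKBR3 arrays. SKBR3 had 1764 calls without siChe-1 replicate 2. List calls ran from 6 to 9 in SKBR3, 10 to 11 in MDA-468 and 4 to 7 for the difference (7 without either SKBR3 siChe-1 array). AATF ran from -0.717 to -0.601 in SKBR3 and from -1.774 to -1.669 in MDA-468. An SKBR3 group left with 1 array is assumed to vary like the other groups.

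No sign was found that the replicate numbers pair the samples. The shared axis of replicate deviations could hide a pairing, so the check does not exclude one. Deviations of same-numbered arrays from their group means correlated with r = -0.556 in SKBR3 and -0.491, 0.000965 and -0.275 in MDA-468, and 0 of 6 MDA-468 arrays correlated best with their own number. With the replicate block SKBR3 had 1248 calls, the difference 1104 and shared calls 845. Crossing the numbers in SKBR3 gave 4270 calls there against 3054.

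Results that changed sign were not past the threshold in the main fit or in the setting where the sign changed, and the cause was not tested: the CDKN1A difference (0.008522 after quantile normalization), MDM2 in MDA-468 (-0.02304 after centring, and -0.06012 without siChe-1 replicate 3 to 0.09 without replicate 1), CFLAR in SKBR3 (0.1647 with the probe set of lowest mean, and -0.5134 without siChe-1 replicate 1 to -0.05683 without replicate 2), TP73 in both lines (-0.006129 without SKBR3 siChe-1 replicate 2 to 0.2428 without replicate 1) and TP73 in MDA-468 (-0.04505 without siChe-1 replicate 1 to 0.03387 without siControl replicate 3, and 0.02586 without siChe-1 replicate 3). Without either SKBR3 siChe-1 array that group has no replicate, so only the values are given for CFLAR and TP73 in those fits. Without the interferon-stimulated list 3014 genes were called in SKBR3 and 5568 in MDA-468.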

Other observations

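The 4 lists below were chosen after the values were seen, so their counts describe these arrays and are no independent evidence of a direction. Antigen presentation genes rose in 14 of 15 measured in each line, with medians of 2.12 in SKBR3 and 1.17 in MDA-468; CALR was not called. TAP1, the peptide transporter, rose by 3.23 ± 0.10 (log2 fold change ± SE) and 2.71 ± 0.08, the immunoproteasome gene PSMB9 by 2.85 and 2.31, NLRC5, a regulator of class I genes, by 2.29 and 1.78, and B2M by 1.05 and 1.17. PSMB8 rose by 3.49 in SKBR3 and 0.54 in MDA-468 (adjusted p = 2.96e-05 for the difference), whereas ERAP2 rose further in MDA-468, by 3.24 against 2.19 (adjusted p = 0.00177).

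Of 12 listed interferon genes, 4 passed the filter on mean level, which their own values on the siChe-1 arrays helped them to pass, and these 4 rose in both lines. With no filter, counted after the data were seen, 8 of the 11 with a probe set rose in SKBR3 and 4 in MDA-468. IFNB1 rose by 6.30 ± 0.17 in SKBR3 and 3.93 ± 0.14 in MDA-468, and IFNL1 by 6.47 ± 0.13 and 4.85 ± 0.10; IFNL2 and IFNL3 are near-identical and their separate values (6.46 and 5.06 in SKBR3) are uncertain. Among 11 nucleic acid sensors and adaptors 7 rose in SKBR3 and 8 in MDA-468, with RIGI at 5.65 and 4.14, IFIH1 at 4.14 and 4.07 and TLR3 at 3.43 and 1.55, while MAVS was at -0.24 in both lines and was called in MDA-468 (adjusted p = 0.02). Of 11 inflammatory cell death factors 9 rose in SKBR3 and 10 in MDA-468, among them CASP1 (2.11 and 1.46), CASP4 (1.64 and 0.91) and MLKL (1.75 and 1.24); RIPK3 was at 0.15 and 0.04 and was not called.

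Besides AATF, 149 genes were called lower in both lines and fell in each at least as far as AATF fell in SKBR3. Of these, 9 fell at least as far as AATF in the same line, in both lines, among them ATPSCKMT (-1.64 in SKBR3 and -1.86 in MDA-468), GET1 (-1.34 and -1.87), PRR11 (-1.28 and -1.74) and AGR2 (-0.90 and -2.04). The sequence of the AATF duplex was not used here.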
